A study of Danio rerio with 20 samples.

How the data were processed

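Skin of male zebrafish was profiled by RNA-seq in 20 libraries, 5 in each of 4 groups that cross age (1 or 3 years) with exercise (none or swim tunnel), per the labels. Libraries were made from total RNA with a TruSeq RNA v2 kit, per the labels' protocols, a kit that does not mark strand, so reads from overlapping or antisense genes cannot be told apart. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 and the genome build GRCz10. The annotation, the settings and any filter on reads are not given in the sources used here, nor are the length and speed of swimming, the hour of sampling or the housing of the fish.

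The main values are the deposited whole-number counts per gene, 1 column per library, which the authors did not normalise as far as the values show: the column totals differ. The authors also deposited RPKM values. In these, the gene length implied by count and RPKM had a coefficient of variation of 22.6% across libraries over 8193 genes when each library's own total was used, and of 0.00249% when the 20 library totals were taken in turn down the gene list. Depth was therefore not removed per library in the deposited RPKM, whose values were 0.558 to 1.79 times those computed with the own total. The deposited RPKM was used in 1 alternative, and to recover gene lengths for another. Gene IDs were paired with symbols from a separate name table, which gives some zebrafish genes symbols in capitals and some symbols to several genes. Of 32105 genes 26269 had a symbol, and where 1 symbol names several genes the ID is printed with it. No genome sequence was used and no coordinates are given.

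All 20 libraries entered 1 model of 4 group means in edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr filter (20788 genes left) and robust quasi-likelihood F-tests on 16 residual degrees of freedom. The biological coefficient of variation was 34.7%. The 7 comparisons were exercise at each age, age with and without exercise, the difference of the exercise effect between ages, and the exercise and age effects averaged over the other factor. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. No covariate was used, since the labels name no batch. Replicate numbers follow accession order and pair no samples. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 47.8.

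Gene lists numbering 44, of cell types and pathways, were tested with camera in limma 3.58.1, with the preset and with an estimated correlation between genes. Their 1050 entries matched 1188 genes, since 1 symbol can match several genes. The score of a list in a library is the mean log2 CPM of its members. Scores, the mitochondrially encoded share, the share of the 100 most abundant genes and total counts were compared between groups by two-sided exact permutation tests over all 252 assignments of 5 against 5, with Benjamini-Hochberg adjustment over 188 tests. The lists, the comparisons, the rule for named genes and the alternative settings were fixed before the data were examined. The rule took, per comparison, the 8 highest and 8 lowest log2 fold changes (5 each for averaged and difference comparisons) among called genes with an assigned symbol and at least 5 CPM in the higher group, and up to 4 called members of each list by p, or the member of lowest p where none passed. Where fewer than 10 genes passed it took all of them and the 5 of lowest p. The text prints a selection of the genes so named.

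The alternative settings were RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma voom with quality weights, limma-trend on the deposited RPKM, the compared groups alone, the fast skeletal muscle score as a covariate, surrogate variables from sva 3.50.0, and each library left out in turn. RPKM recomputed with each library's own total, and a hepatocyte score as a covariate, were added after the data were examined. The hepatocyte list had 31 entries, of which 28 genes were measured, 1 of them also in another list. The edgeR test was tried for each comparison on counts simulated with the mean of each gene over all libraries and the real library sizes. DESeq2, limma voom, limma-trend, both covariates and camera were tried for exercise at 1 year alone. No surrogate variable was found in simulated counts, so that setting was not tested. With changes of 2-fold and 4-fold the edgeR test found 53.7% and 84.8% of changed genes for exercise at 1 year and called 7 unchanged genes. It found 52.2% and 93.9% (3 unchanged called) for exercise at 3 years, 49.3% and 77.3% (2) for age without exercise, and 46.3% and 90.9% (0) for age with exercise. For exercise at 1 year DESeq2 found 67.2% and 90.9% and called 23 unchanged genes, and limma voom called 6. camera called 2 of 2 changed lists and 0 of 40 random lists. The simulated genes varied independently, so this does not test camera on lists of correlated genes. Total counts of 29280697 to 52437698 per library leave the spread between samples, which the model estimates, as the main source of error for abundant genes. Plots and permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.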

Results

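RNA was sequenced from the skin of 20 male zebrafish (Danio rerio), 1 library per sample. The labels give 4 groups of 5: 1-year and 3-year fish that were left unperturbed, and 1-year and 3-year fish that were exercised in a swim tunnel, a chamber in which fish swim against a current. Per the labels the strain is AB JxTu. The fish of each age are necessarily different individuals, and nothing ties a sample of one group to a sample of another. The p-values therefore measure the spread between samples within groups. For single genes the model takes this spread as common to all 4 groups. Counts with the compared groups alone are given below where they moved. Total counts per library ranged from 31272180 to 43187976 in unexercised 1-year fish, 29633656 to 52437698 in exercised 1-year fish, 36616292 to 50756160 in unexercised 3-year fish and 29280697 to 42117170 in exercised 3-year fish. Levels are in CPM, counts scaled to a common library total with TMM-scaled library sizes, and are given as mean ± SD with n = 5 per group. Fold changes of single genes are log2 values with their standard error (SE), and adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 20788 genes. Adjusted p-values of gene lists are from camera, adjusted over 44 lists, with a preset correlation between genes unless an estimated correlation is named.

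The first principal component held 21.9% of the variance and the second 12.7%. Exercised 1-year libraries lay at 39.1 to 80.8 on the first component, against -3.1 to 0 in 4 unexercised 1-year libraries and 34.8 in replicate 5. On the second component, replicate 1 of the unexercised 3-year fish lay at 53.7, within the range of the unexercised 1-year libraries (28.8 to 54.5), while the other 4 unexercised 3-year libraries lay between -4.1 and 8.5. The 100 most abundant genes took 35.9 ± 0.874% of counts in unexercised and 39.2 ± 0.828% in exercised 1-year fish (SD, n = 5, two-sided exact permutation p = 0.00794, adjusted p = 0.0746 over 188 tests of 47 measures per library), and 36.8 ± 0.638% and 36.7 ± 1.51% in unexercised and exercised 3-year fish. None of the 188 exact tests passed an adjusted 0.05. The smallest p that 5 against 5 allows is 0.00794. The count column of replicate 1 of the unexercised 1-year fish is named muscle, while its label says skin. It held 46947 CPM of the keratin krt5, within the 34453 to 55120 CPM of the other 19 libraries, 2259 CPM of the keratin krt4, below the 2411 to 4925 CPM of the others, and 1369 CPM of the muscle creatine kinase ckma (563 to 3506 CPM in the others). The CPM of these 3 genes here use plain library totals, without TMM scaling.

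**Figure D1:**
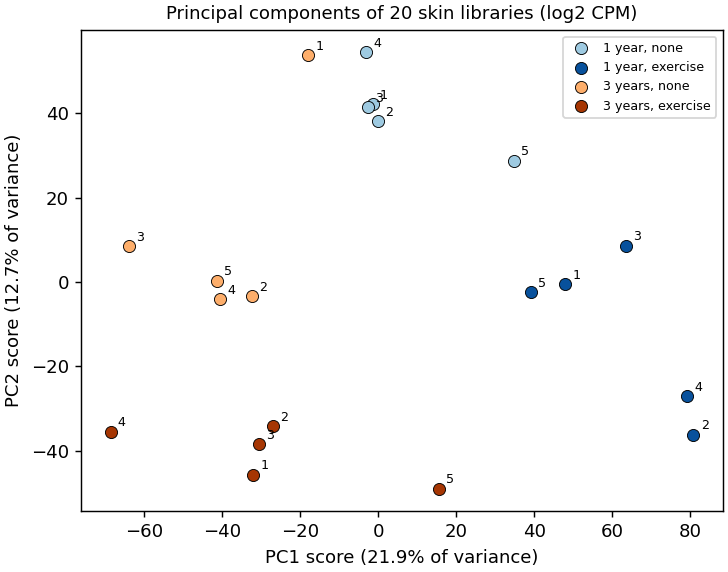
Scores of the 20 skin libraries on the first (21.9% of variance) and second (12.7%) principal components of log2 CPM, with 1 point per library, coloured by age and exercise and numbered by replicate. Exercised 1-year libraries lie at 39.1 to 80.8 on the first component, and replicate 1 of the unexercised 3-year group lies at 53.7 on the second, among the unexercised 1-year libraries.

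The first comparison asked which transcripts differed with exercise at 1 year. Some transcripts of the basal epidermis rose. TP63 (ENSDARG00000044356), a transcription factor of basal keratinocytes, had 358 ± 62.5 CPM in unexercised and 869 ± 203 CPM in exercised fish (SD, n = 5 each), a log2 fold change of 1.28 (SE 0.19, adjusted p = 0.000743). The hemidesmosome integrins itga6b and ITGB4 rose by 1.87 (SE 0.32) and 1.78 (SE 0.32). Of 14 measured basal keratinocyte genes, 7 rose and 7 did not pass the test, with 8 higher when adjusted over the list alone. Their median was 0.59 (camera adjusted p = 2.97e-07), and adjusted p = 0.191 with an estimated correlation. Of 18 superficial keratinocyte genes, 3 rose, among them the desmosomal plaque proteins PPL by 1.69 (SE 0.29), from 659 ± 182 to 2121 ± 994 CPM, and evpla by 2.2 (SE 0.40), and 1 fell, with 6 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.785 with an estimated correlation).

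Some matrix and bone genes also rose at 1 year. In the dermal matrix list 7 of 34 genes rose (10 adjusted over the list alone), including the collagen prolyl hydroxylase subunit P4HA1 by 1.59 (SE 0.25) and the collagen crosslinking enzyme LOX by 1.39 (SE 0.32), with a list adjusted p = 4.93e-05. In the scale osteoblast list 4 of 15 rose (6 adjusted over the list alone), including osteocalcin (bglap) by 1.68 (SE 0.36), with a list adjusted p = 0.00507. In both lists adjusted p = 0.785 with an estimated correlation. Genes of the hypoxia and glycolysis list rose in 7 of 35 (8 adjusted over the list alone), among them the hypoxia-inducible ANKRD37 by 3.53 (SE 0.56), the prolyl hydroxylase EGLN3 by 1.58 (SE 0.24) and the glucose transporter SLC2A1 (ENSDARG00000007412) by 0.97 (SE 0.20), with a list adjusted p = 0.00169. Of 103 oxidative phosphorylation genes 8 rose, 1 of them when adjusted over the list alone. Their median was 0.30 (adjusted p = 4.33e-08), with SDHA higher by 0.53 (SE 0.10). Of 13 mitochondrially encoded genes 5 rose (9 adjusted over the list alone, list adjusted p = 0.000118), with MT-CO1 higher by 0.51 (SE 0.15). The hypoxia, oxidative phosphorylation and mitochondrial lists had adjusted p = 0.785 with an estimated correlation. In the fatty acid oxidation list 8 of 32 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.00318, and adjusted p = 0.785 with an estimated correlation): the uncoupling protein UCP1 rose by 3.01 (SE 0.72) and the fatty acid importer CPT1A fell by 0.62 (SE 0.13). With the hepatocyte score described next as a covariate, the median of this list went from 0.30 to 0.16 and the list did not pass.

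Liver-type transcripts were high in part of the exercised 1-year libraries. The apolipoprotein apoa4b.1 rose by 4.23 (SE 0.72, adjusted p = 0.0014), the liver pyruvate kinase PKLR by 4.03 (SE 0.77) and apoa2 by 4.01 (SE 0.75). apoa2 had 25.6 ± 3.83 CPM in unexercised and 411 ± 425 CPM in exercised fish. In the complement and antimicrobial list 8 of 36 genes rose, as many when adjusted over the list alone, including itln1 by 3.33 (SE 0.73) and the complement gene c3a.5 by 2.95 (SE 0.73), with a median of 1.36 (adjusted p = 0.000959, and adjusted p = 0.785 with an estimated correlation). With the mean log2 CPM of 28 hepatocyte genes as a covariate, a list made after the data were examined, the median of the complement list was -0.27 and the list did not pass. The printed hepatocyte score, here and below the mean log2 of CPM plus 1, was 4.94, 5.61 and 6.62 in exercised replicates 1, 2 and 3. It was 3.24 and 3.51 in replicates 4 and 5. The unexercised 1-year libraries averaged 2.83 ± 0.26 (SD, n = 5).

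**Figure D2:**
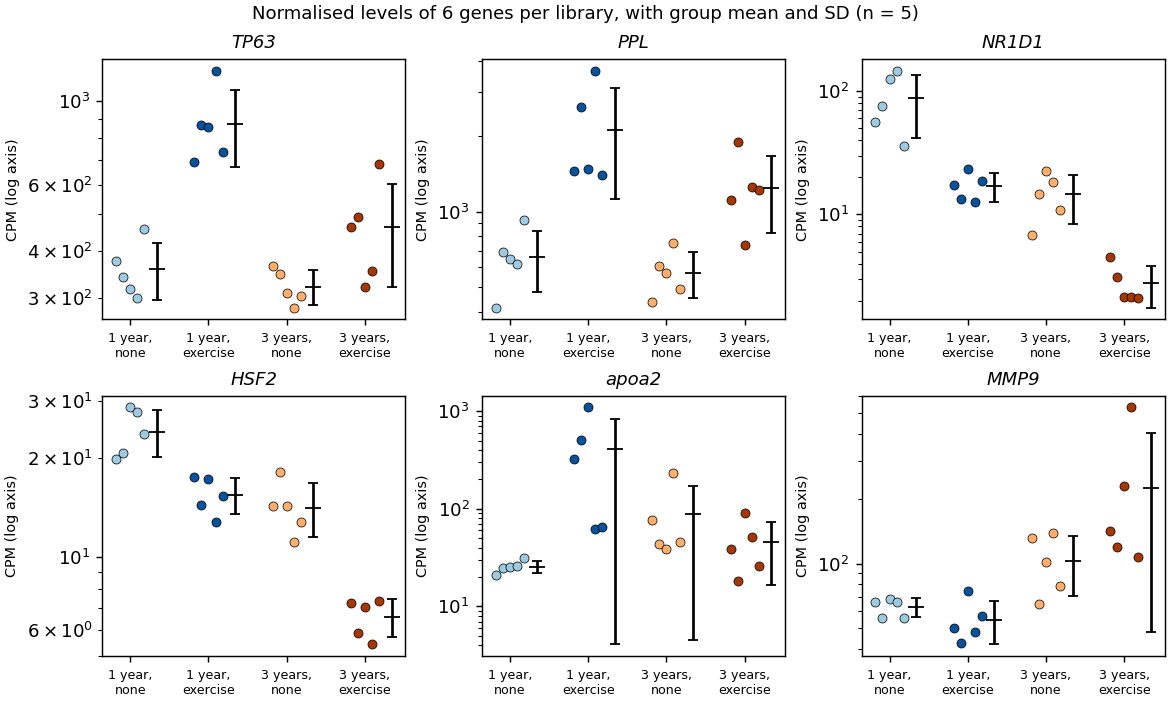
CPM per library on a log axis for TP63, PPL, NR1D1, HSF2, apoa2 and MMP9 in the 4 groups, with 1 point per library and the group mean and SD (n = 5) as a dash and bars, the lower bar ending just above 0 where the SD exceeds the mean. PPL averaged 659, 2121, 572 and 1249 CPM and NR1D1 87.9, 17.1, 14.7 and 2.80 CPM in unexercised and exercised 1-year and unexercised and exercised 3-year fish.

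Some antiviral, replication and clock genes fell with exercise at 1 year. In the interferon response list 11 of 38 genes fell (15 adjusted over the list alone), including ifit10 by 2.78 (SE 0.71, adjusted p = 0.014), RSAD2 by 2.42 (SE 0.65, adjusted p = 0.0168) and the viral RNA sensor DHX58 by 1.94 (SE 0.49), with a median of -0.96 (adjusted p = 4.33e-08). In the cell cycle list 6 of 42 fell, as many when adjusted over the list alone, including the replicative helicase subunits MCM2 by 1.96 (SE 0.34) and MCM5 by 1.91 (SE 0.37), with a median of -0.54 (adjusted p = 4.64e-06). Both lists had adjusted p = 0.785 with an estimated correlation. CDCA7, another cell division gene, fell by 2.64 (SE 0.43). Of 40 clock genes 11 fell and 5 rose, and 14 and 5 when adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.785 with an estimated correlation). The clock list did not pass with the hepatocyte covariate, with a median of -0.305. The clock repressor NR1D1 (ENSDARG00000033160) went from 87.9 ± 46.4 to 17.1 ± 4.4 CPM, a log2 change of -2.36 (SE 0.37, adjusted p = 0.000941), rorca fell by 1.37 (SE 0.24) and cry3b rose by 1.46 (SE 0.21). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 3.11 (SE 0.58), from 548 ± 327 to 63.5 ± 44.4 CPM. The glucocorticoid receptor NR3C1 fell by 1.14 (SE 0.22), foxo3a by 1.26 (SE 0.17), the unfolded protein sensor EIF2AK3 by 1.04 (SE 0.14) and bcl11ba by 1.70 (SE 0.30). ZBTB16, the mTOR inhibitor DEPTOR and the growth factor receptor IGF1R (ENSDARG00000034434) rose by 2.77 (SE 0.44), 1.64 (SE 0.28) and 1.28 (SE 0.24). The endothelial adhesion gene pecam1a rose by 0.72 (SE 0.18) and the tropomyosin tpm3 by 0.46 (SE 0.13).

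In all, 3227 of 20788 genes passed at 1 year by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 1532 higher (47.5%) and 1695 lower, and 1104 of them by more than 2-fold. Over all genes, the values of the 5 exercised and 5 unexercised libraries did not overlap in 2667 (12.8%), which chance gives for 0.794% of genes. Where RPKM was recomputed with each library's own total, 16.9% of the called genes were higher, and the median log2 fold change of all genes was -0.136, against 0.0117 with TMM scaling. Of the 39 genes named for this comparison, MT-CO1, tpm3 and RSAD2 lost the call in at least 1 of the 20 fits without a library (highest adjusted p = 0.07), and none of the 39 reversed in those fits. limma voom called 5 complement genes, against 8 by edgeR, and 34 oxidative phosphorylation genes, against 8. The count was 2109 without unexercised replicate 1, 1909 without exercised replicate 2 and 2016 without exercised replicate 4, 1952 with the hepatocyte covariate, 433 on the deposited RPKM and 2 with surrogate variables.

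The second comparison asked the same of 3-year fish. The laminin chain lamb3 rose by 1.77 (SE 0.39) and itga6b by 1.32 (SE 0.32). Of 14 basal keratinocyte genes 3 rose (6 adjusted over the list alone), with a median of 0.48 (adjusted p = 4.05e-05). The desmosomal cadherin dsc2l rose by 1.99 (SE 0.40). In the dermal matrix list 1 of 34 genes rose, the glycoprotein TNC (ENSDARG00000021948) by 1.70 (SE 0.39), against 13 adjusted over the list alone, and the median was 0.50 (adjusted p = 9.07e-08). Both lists had adjusted p = 0.418 with an estimated correlation. The lysyl oxidase-like gene loxl2a rose by 2.37 (SE 0.47), scpp7, of the secretory calcium-binding phosphoprotein family, by 2.07 (SE 0.35), and PHEX, a regulator of mineralisation, by 0.75 (SE 0.18). In the hypoxia and glycolysis list 3 of 35 rose, and 3 adjusted over the list alone: ANKRD37 by 2.29 (SE 0.56, adjusted p = 0.0499), VEGFA (ENSDARG00000103542) by 1.48 (SE 0.34) and SLC2A1 (ENSDARG00000007412) by 0.86 (SE 0.20). That list had adjusted p = 0.00984, and adjusted p = 0.418 with an estimated correlation, and it did not pass with the fast skeletal muscle score as a covariate (median 0.077).

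Muscle transcripts were higher in part of the exercised 3-year libraries. In the fast skeletal muscle list 1 of 28 genes rose, the myosin heavy chain myhz2 by 2.48 (SE 0.55, adjusted p = 0.0372), and 11 when adjusted over the list alone. The median was 1.15 (adjusted p = 1.46e-08, and adjusted p = 0.418 with an estimated correlation). The score of the list was 5.85 ± 0.66 in unexercised and 6.81 ± 1.12 in exercised fish (SD, n = 5, two-sided exact permutation p = 0.159). tpm3, of the slow muscle list, rose by 0.52 (SE 0.13). The median of 103 oxidative phosphorylation genes was 0.23 (adjusted p = 2.87e-07, and adjusted p = 0.572 with an estimated correlation). No gene of that list passed edgeR's test, either over all genes or over the list alone, while 15 had an unadjusted p below 0.05 and DESeq2 called 1 and limma voom 0. With the fast skeletal muscle score as a covariate the median was 0.02 and the list did not pass. The ion pump gene atp1a1a.5, from the ionocyte list, rose by 2.02 (SE 0.39).

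Clock genes that passed with exercise at 3 years mostly fell. Of 40 clock genes 8 fell and 1 rose (10 and 1 adjusted over the list alone, list adjusted p = 0.000208, and adjusted p = 0.418 with an estimated correlation). NR1D1 went from 14.7 ± 6.25 to 2.80 ± 1.04 CPM, a log2 change of -2.4 (SE 0.38, adjusted p = 0.0118). The clock repressors ciarta and PER1 (ENSDARG00000012499) fell by 2.21 (SE 0.34) and 1.29 (SE 0.17), and cry-dash, a cryptochrome family gene, by 0.92 (SE 0.16). The heat shock factor HSF2 fell by 1.1 (SE 0.15, adjusted p = 0.00399), from 14.1 ± 2.62 to 6.58 ± 0.879 CPM, while the heat shock and chaperone list of 38 genes had a median of 0.25 (2 fell, and 4 rose and 2 fell adjusted over the list alone, list adjusted p = 0.043, and adjusted p = 0.418 with an estimated correlation), a list that did not pass with the hepatocyte covariate (median 0.22). The proapoptotic gene bbc3 fell by 1.52 (SE 0.34), CPT1A by 0.52 (SE 0.13), otoa by 3.44 (SE 0.76), TCIM (ENSDARG00000076858) by 2.94 (SE 0.63) and pogza by 1.64 (SE 0.33). Of 82 ribosomal protein genes 1 fell, RPL12 by 0.30 (SE 0.07), and none adjusted over the list alone, with a median of -0.18 (adjusted p = 2.92e-08, and adjusted p = 0.418 with an estimated correlation). The myeloid transcription factor SPI1 rose by 0.95 (SE 0.23), the osteoclast fusion gene ocstamp by 2.38 (SE 0.56), the leptin gene lepb by 2.09 (SE 0.50), MANF, a secreted factor of the endoplasmic reticulum stress response, by 0.89 (SE 0.21), and the myelin gene PMP22 by 0.98 (SE 0.19).

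At 3 years 275 genes passed, 167 higher (60.7%) and 108 lower, 150 of them by more than 2-fold. The groups did not overlap in 4.32% of all genes, against 0.794% by chance. On the deposited RPKM 18.5% of 27 called genes were higher, and the median log2 fold change of all genes was -0.158, against 0.0103 with TMM scaling. The share higher was 50% of 260 genes on RPKM with own totals and 42% of 50 with the compared groups alone. Without unexercised 3-year replicates 1, 2, 3, 4 and 5 it was 40.5%, 43.6%, 36.8%, 53.6% and 41.2%. In the other fits without a library it ran from 56.1% to 68.2%. Of the 29 genes named for this comparison, NR1D1, ciarta, PER1 (ENSDARG00000012499), cry-dash, HSF2 and scpp7 kept the call in all 20 fits without a library and 23 lost it in at least 1 (highest adjusted p = 0.111), with none of the 29 reversed. With limma voom 6 of the 29 kept the call, and with the compared groups alone 6. With the muscle covariate 8 kept it, and with the hepatocyte covariate 8. The count was 152 without unexercised 1-year replicate 2, 90 without exercised 3-year replicate 5, and 42, 78, 57, 110 and 68 without unexercised 3-year replicates 1, 2, 3, 4 and 5. Of the lists above, limma voom called 1 basal keratinocyte, 4 clock and 0 hypoxia and glycolysis genes, against 3, 9 and 3 by edgeR, 5, 11 and 4 by DESeq2 and 7, 15 and 14 at an unadjusted p below 0.05. The count over all genes was 1298 with DESeq2, 39 with limma voom and quality weights, 50 with the compared groups alone, 54 with the muscle covariate, 57 with the hepatocyte covariate and 9 with surrogate variables.

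**Figure D3:**
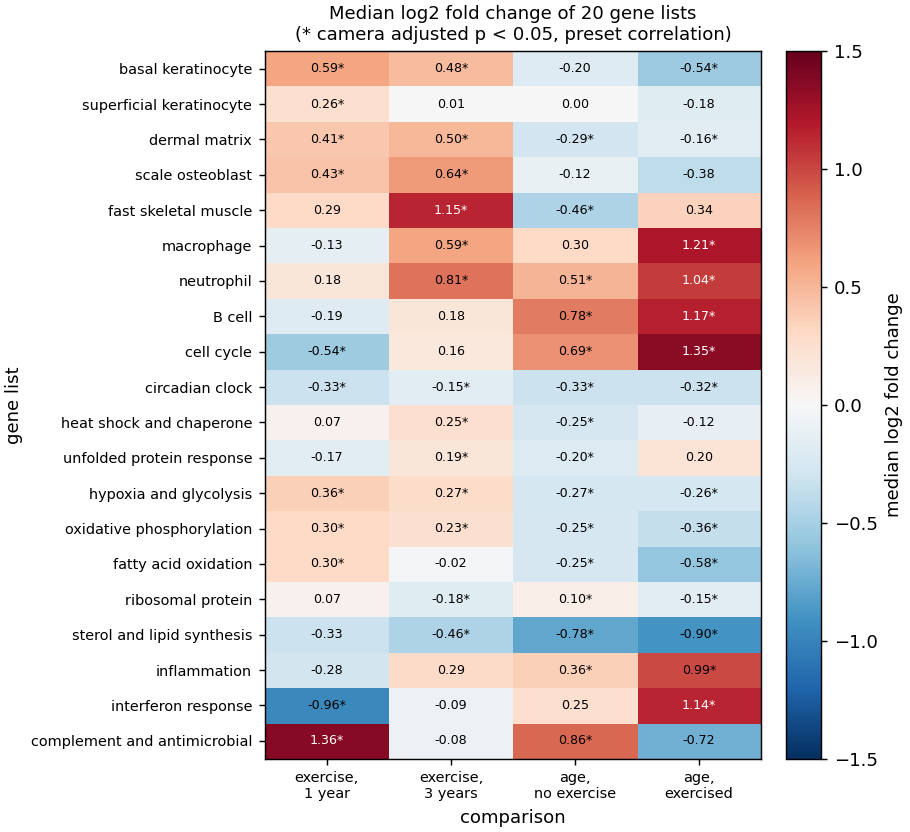
Median log2 fold change of the measured members of 20 gene lists, by list and comparison, with colour from lower (blue) to higher (red) and an asterisk where camera's adjusted p with a preset correlation is below 0.05. The cell cycle list has a median of -0.54 with exercise at 1 year and 1.35 with age among exercised fish, and no list passes with an estimated correlation.

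The third comparison set unexercised 3-year fish against unexercised 1-year fish. Clock genes were among those called. NR1D1 fell by 2.58 (SE 0.37, adjusted p = 0.00297), the output regulators dbpa and dbpb by 1.42 (SE 0.23) and 1.38 (SE 0.21), ciartb by 1.35 (SE 0.26), CRY2 by 1.14 (SE 0.14, adjusted p = 0.000901) and PER1 (ENSDARG00000012499) by 1.29 (SE 0.17, adjusted p = 0.00115), while cry3b rose by 1.46 (SE 0.21) and rorcb by 1.58 (SE 0.37). Of 40 clock genes 7 fell and 4 rose, and 18 and 9 when adjusted over the list alone (adjusted p = 0.00393, and adjusted p = 0.739 with an estimated correlation). Some single immune genes were higher at 3 years. In the neutrophil, macrophage, T cell, B cell, inflammation, interferon response and antigen presentation lists edgeR called 0 members. The properdin gene cfp, of the alternative complement pathway, had 6.43 CPM at 1 year and 20.0 ± 5.53 CPM at 3 years (SD, n = 5), a log2 fold change of 1.64 (SE 0.19, adjusted p = 0.000725). The chemokine receptor CXCR3 rose by 1.25 (SE 0.30), ms4a17a.7 by 1.59 (SE 0.28), the endothelial gene plvapb by 0.88 (SE 0.18), the translation repressor eif4ebp3 (ENSDARG00000054916) by 1.02 (SE 0.20) and urgcp by 1.36 (SE 0.31). The B cell receptor gene cd79a did not pass (log2 1.57, SE 0.54, adjusted p = 0.152).

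Single genes that fell with age in unexercised fish came from several lists. The triglyceride synthesis enzyme DGAT2 fell by 1.93 (SE 0.38), scpp7 by 1.88 (SE 0.34), the matricellular gene CCN4 by 1.52 (SE 0.32), the aldo-keto reductase AKR1B1 (ENSDARG00000006215) by 1.31 (SE 0.25), the mucous cell gene AGR2 by 1.2 (SE 0.28), HSF2 by 0.77 (SE 0.14), the hexokinase HK1 by 0.48 (SE 0.10) and the proteasome subunit PSMD11 (ENSDARG00000005134) by 0.60 (SE 0.13). Of 103 oxidative phosphorylation genes 1 rose, COX4I2 by 0.94 (SE 0.15, adjusted p = 0.00618), and adjusted over the list alone 15 fell and 1 rose. The median was -0.25 (adjusted p = 5.22e-13, and adjusted p = 0.739 with an estimated correlation). The fast skeletal muscle list was lower too, with a median of -0.46 (adjusted p = 0.00092, and adjusted p = 0.739 with an estimated correlation) and scores of 6.41 ± 0.48 at 1 year and 5.85 ± 0.66 at 3 years (SD, n = 5, two-sided exact permutation p = 0.159). With that score as a covariate the oxidative phosphorylation median was -0.165 and the list still passed. In the sterol and lipid synthesis list no gene passed edgeR's test over all genes or over the list alone, FASN having -1.1 (SE 0.39, adjusted p = 0.161), with 6 at an unadjusted p below 0.05 and 0 by DESeq2 or limma voom, and the median of 33 was -0.78 (adjusted p = 5.45e-05). No cell cycle gene passed either test, bub1 having 1.12 (SE 0.37, adjusted p = 0.138), with 17 at an unadjusted p below 0.05 and 0 by DESeq2 or limma voom, and the median of 42 was 0.69 (adjusted p = 0.000119). In the complement and antimicrobial list no gene passed edgeR's test over all genes, itln1 having 2.61 (SE 0.72, adjusted p = 0.0827), with 7 at an unadjusted p below 0.05 and 4 each by DESeq2 and limma voom, and 5 of 36 rose when adjusted over the list alone (median 0.86, adjusted p = 9.04e-05). With the hepatocyte covariate that median was 0.052 and the list did not pass. In these 3 lists adjusted p = 0.739 with an estimated correlation. The hepatocyte score was 3.63 ± 0.94 in unexercised 3-year fish against 2.83 ± 0.26 at 1 year (SD, n = 5, two-sided exact permutation p = 0.0476). In unexercised 3-year replicate 4 the score was 5.21, and in the others of that group it was 2.92 to 3.72.

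In total 201 genes passed with age in unexercised fish, 103 higher (51.2%) and 98 lower, 96 of them by more than 2-fold. The groups did not overlap in 5.08% of all genes, against 0.794% by chance. On the deposited RPKM 84.8% of 46 called genes were higher, and the median log2 fold change of all genes was 0.20, against 0.0206 with TMM scaling. Recomputed with each library's own total, RPKM gave 64.2% higher. Of the 23 genes named here as past the test, NR1D1, dbpa, dbpb, CRY2, PER1 (ENSDARG00000012499), cry3b, cfp, ms4a17a.7 and COX4I2 kept the call in all 20 fits without a library and 14 lost it in at least 1 (highest adjusted p = 0.129), with none reversed. The count was 67, 43, 99 and 48 without unexercised 1-year replicates 1, 2, 4 and 5, and 393, 87, 57, 95 and 60 without unexercised 3-year replicates 1, 2, 3, 4 and 5. It was 842 with DESeq2, 933 with limma voom and quality weights, 129 with the compared groups alone and 77 with the hepatocyte covariate.

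The fourth comparison set exercised 3-year fish against exercised 1-year fish. Most replication and mitosis genes listed were higher at 3 years. In the cell cycle list 35 of 42 genes rose (38 adjusted over the list alone), with a median of 1.35 (adjusted p = 3.31e-16, and adjusted p = 0.368 with an estimated correlation), while limma voom with quality weights called 19. The score of the list was 2.31 in exercised 3-year replicate 5, below the mean of 2.67 in exercised 1-year fish, and 3.50 to 4.59 in the other 4 (two-sided exact permutation p = 0.0397, n = 5, adjusted p = 0.159). The proliferation marker mki67 rose from 19.5 ± 4.83 to 65.6 ± 36.3 CPM (SD, n = 5 each), by 1.75 (SE 0.35, adjusted p = 0.00458), MCM7 by 0.90 (SE 0.14), CCNA2 by 1.69 (SE 0.35) and h2ax by 1.25 (SE 0.24). Some immune cell genes rose too. In the macrophage list 12 of 22 rose, and 12 adjusted over the list alone, among them SPI1 by 1.55 (SE 0.24), MFAP4 (ENSDARG00000090783) by 2.24 (SE 0.40), c1qa by 1.68 (SE 0.32) and c1qb by 1.36 (SE 0.25), with a list adjusted p = 7.12e-07. In the neutrophil list 6 of 10 rose, the same number adjusted over the list alone, among them the interleukin gene il1b by 2.35 (SE 0.44) and CSF3R by 1.25 (SE 0.27), with a list adjusted p = 0.000157. In the inflammation list 15 of 40 rose, and 22 rose and 1 fell when adjusted over the list alone (adjusted p = 3.25e-07). Of 9 B cell genes 4 rose, and 4 adjusted over the list alone, including the immunoglobulin gene ighm by 3.12 (SE 0.77) and cd79a by 2.46 (SE 0.57), with a list adjusted p = 0.000767. In these 4 immune lists adjusted p = 0.368 with an estimated correlation.

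In the interferon response list 17 of 38 genes rose with age among exercised fish (27 adjusted over the list alone), with mxf higher by 2.99 (SE 0.53) and ifit15 by 3.67 (SE 0.91) and a median of 1.14 (adjusted p = 9.15e-08, and adjusted p = 0.523 with an estimated correlation), while limma voom with quality weights called 4. The score was 2.74 in exercised 3-year replicate 5, below the 2.96 to 3.61 of exercised 1-year fish, and 4.17 to 5.54 in the other 4 (two-sided exact permutation p = 0.0873, n = 5, adjusted p = 0.231). In the matrix protease list 6 of 15 genes rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.00904), and in the osteoclast list 2 of 6 rose (3 adjusted over the list alone, adjusted p = 0.0184), both with adjusted p = 0.368 with an estimated correlation. The gelatinase MMP9 rose by 2.05 (SE 0.36), from 54.4 ± 12.2 to 225 ± 177 CPM, mmp13b by 3.06 (SE 0.58), ocstamp by 4.32 (SE 0.65, adjusted p = 0.000859) and the acid phosphatase ACP5 by 2.84 (SE 0.58). lepb rose by 3.2 (SE 0.54), the complement genes cfbl by 2.15 (SE 0.34) and c4 by 1.4 (SE 0.27), and the haem oxygenase HMOX1 by 1.09 (SE 0.24). The class II gene mhc2dga was listed at 0.109 CPM in exercised 1-year and 136 ± 151 CPM in exercised 3-year fish, and nkl.2, a natural killer lysin of a multigene family, had a fitted 6.26 (SE 1.54). Reads of such families can be split between near-identical copies, so both genes are uncertain.

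Some metabolic genes fell with age among exercised fish. Of 103 oxidative phosphorylation genes 28 fell and 1 rose (37 and 1 adjusted over the list alone), including SDHA by 0.64 (SE 0.10) and SDHB by 0.67 (SE 0.14), with a median of -0.36 (adjusted p = 3.24e-12, and adjusted p = 0.506 with an estimated correlation). In the fatty acid oxidation list 14 of 32 fell and 1 rose (15 and 1 adjusted over the list alone), CPT2 by 0.87 (SE 0.15), with an adjusted p = 8.51e-08, and adjusted p = 0.368 with an estimated correlation. In the sterol and lipid synthesis list 5 of 33 fell (4 adjusted over the list alone), including srebf2 by 1.16 (SE 0.25) and HSD17B7 by 1.35 (SE 0.36), with an adjusted p = 2e-06, and adjusted p = 0.523 with an estimated correlation. The peroxidase gpx1b fell by 1.34 (SE 0.20), the guanine metabolism gene pnp4a of iridophores by 2.39 (SE 0.34) and GPNMB by 1.22 (SE 0.25). TP63 fell by 0.91 (SE 0.19), krt15 by 0.97 (SE 0.24) and POSTN (ENSDARG00000104267) by 1.05 (SE 0.19). In the dermal matrix list 8 of 34 fell and 3 rose (10 and 4 adjusted over the list alone, adjusted p = 0.0132, and adjusted p = 0.623 with an estimated correlation). Of 14 basal keratinocyte genes 7 fell and 1 rose, the same when adjusted over the list alone (adjusted p = 0.000912, and adjusted p = 0.368 with an estimated correlation). ANKRD37 fell by 2.42 (SE 0.53), DDIT4 by 2.4 (SE 0.63), and the liver-type genes apoa4b.1 by 3.74 (SE 0.70) and PKLR by 3.38 (SE 0.74). Of 28 hepatocyte genes 21 fell. Clock genes went both ways, 18 of 40 falling and 13 rising (18 and 15 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.557 with an estimated correlation). PER1 (ENSDARG00000012499) fell by 1.79 (SE 0.17, adjusted p = 1.93e-05), cry5 by 2.15 (SE 0.22), dbpb by 1.97 (SE 0.21), HSF2 by 1.23 (SE 0.15) and the chaperone hsp90aa1.1 by 1.82 (SE 0.36).

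Among exercised fish 3566 genes passed with age, 2022 higher (56.7%) and 1544 lower, 1593 of them by more than 2-fold. The groups did not overlap in 9.13% of all genes, against 0.794% by chance. This comparison and exercise at 1 year share the exercised 1-year libraries with opposite sign. Of genes called in both, 694 were higher with exercise and lower with age, against 114 for independent lists. Another 659 were lower with exercise and higher with age, against 165, while 2 were higher and 7 lower in both. The shared libraries favour calls in opposite directions, which the values for independent lists do not allow for. The share that was higher was 69.9% of 578 genes on the deposited RPKM and 84.2% on RPKM with each library's own total, where the median log2 fold change of all genes was 0.16, against 0.0249 with TMM scaling. Of the 44 genes named here, mhc2dga (highest adjusted p = 0.0907) and nkl.2 (adjusted p = 0.287 without exercised 3-year replicate 4) lost the call in at least 1 of the 20 fits without a library, and none reversed. The count was 2174 and 2259 without exercised 1-year replicates 2 and 4. It was 1673 with the compared groups alone, 1927 with the hepatocyte covariate and 16 with surrogate variables.

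**Figure D4:**
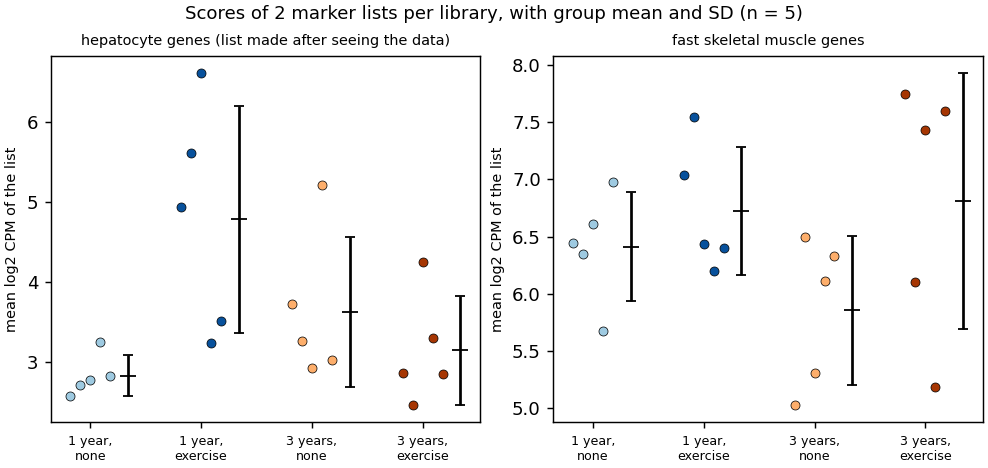
Mean log2 of CPM plus 1 per library of 28 hepatocyte genes, a list made after the data were examined, and mean log2 CPM of the fast skeletal muscle list, by group, with 1 point per library and the group mean and SD (n = 5) as a dash and bars. The hepatocyte score is 4.94, 5.61 and 6.62 in 3 exercised 1-year libraries and 3.24 and 3.51 in the other 2, and the muscle score averages 5.85 in unexercised and 6.81 in exercised 3-year fish.

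The fifth comparison tested whether the exercise effect differed between ages. ENSDARG00000104886, which the name table gives no symbol, had a difference of 1.8 (SE 0.27, adjusted p = 0.0383 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was the only gene past the test. It had 3.74 ± 0.743 CPM in unexercised and 1.64 ± 0.325 CPM in exercised 1-year fish, and 1.72 ± 0.117 and 2.64 ± 0.568 CPM in unexercised and exercised 3-year fish (SD, n = 5). The 5 genes of next lowest p did not pass: FNDC3B had 1.09 (SE 0.18, adjusted p = 0.0617), and dicp1.17, TTC6, kdm6bb and GEMIN5 had 4.53, 1.54, 1.09 and 1.43 (adjusted p = 0.101 each). Genes past the test at one age and not at the other are therefore not shown to differ: MCM2 had 1.82 (SE 0.46, adjusted p = 0.113), ifit10 2.85 (SE 0.96, adjusted p = 0.198), ocstamp 3.80 (SE 0.86, adjusted p = 0.102), EGLN3 -1.76 (SE 0.34, adjusted p = 0.101), UCP1 -3.63 (SE 0.98, adjusted p = 0.12), c3a.5 -3.53 (SE 0.98, adjusted p = 0.131) and myhz2 2.54 (SE 0.75, adjusted p = 0.153).

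By gene list, the difference was higher at 3 years than at 1 year for the cell cycle (median 0.73, adjusted p = 3.22e-08), interferon response (0.80, adjusted p = 4.66e-06), macrophage (0.87, adjusted p = 6.98e-05) and unfolded protein response lists (0.36, adjusted p = 4.66e-06). It was lower for ribosomal protein genes (-0.24, adjusted p = 7.37e-11) and complement genes (-1.5, adjusted p = 0.000285). With the hepatocyte covariate the complement list passed in the other direction, with a median of 0.59. With an estimated correlation these gave adjusted p = 0.618 for the cell cycle and interferon lists and adjusted p = 0.56 for the other 4. Adjusted over the list alone, 5 cell cycle and 8 unfolded protein response genes were higher and 21 ribosomal protein and 4 complement genes lower, while none of these genes passed over all genes by edgeR and none of the interferon or macrophage genes passed either way. At an unadjusted p below 0.05 there were 10 cell cycle, 8 interferon, 8 macrophage, 10 unfolded protein response, 30 ribosomal protein and 17 complement genes, of which DESeq2 called 4, 0, 0, 2, 10 and 5 and limma voom 0. Members of lowest p were HYOU1 (log2 1.15, SE 0.26, adjusted p = 0.102), c1qa (1.41, SE 0.44, adjusted p = 0.174) and rps27a (-0.39, SE 0.10, adjusted p = 0.115). Over all genes 2783 had an unadjusted p below 0.05, and DESeq2 called 498. On simulated counts the test found 29.9% of 2-fold and 54.5% of 4-fold differences. The gene that passed lost the call in 9 of the 20 fits without a library (highest adjusted p = 0.127). The count was 39, 28 and 8 without exercised 3-year replicate 5 and exercised 1-year replicates 5 and 1, 4, 3, 2, 3, 2 and 5 without unexercised 1-year replicate 5, exercised 1-year replicates 3 and 4, unexercised 3-year replicate 4 and exercised 3-year replicates 1 and 2, and 0 without unexercised 1-year replicates 1, 2 and 4, unexercised 3-year replicates 1, 2 and 5 or exercised 3-year replicate 4.

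The exercise effects at the 2 ages share no library. Of genes called at both ages 92 were higher in both, against 12.3 by chance, and 55 lower in both, against 8.81, and none was called in opposite directions (7.96 and 13.6 by chance). The chance values here, and those for the age effects below, take genes as independent. No overlap was counted with permuted labels. Across 20788 genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.253 and Spearman rho = 0.377, with the same sign in 64.9%. With group labels permuted within each age 20 times, r ran from -0.0823 to 0.269, so that 2 of the values, the real one included, were as large. Over 12232 genes with a mean of at least 5 CPM r was 0.394. With the fast skeletal muscle score as a covariate, over all 20788 genes, r was 0.164 and rho 0.26. The age effects without and with exercise shared 59 higher genes, against 10 by chance, and 44 lower genes, against 7.28, with 1 in opposite directions. Their r was 0.433 and rho 0.44, outside the permuted range of -0.286 to 0.178.

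Exercise at 3 years and age without exercise share the unexercised 3-year libraries with opposite sign. Their fold changes had r = -0.213, rho = -0.282 and a covariance of -0.0671, against r = -0.499 and a covariance of -0.0719 in 10 simulations of unchanged groups, a difference of covariances of 0.0048. With those 5 libraries split into 2 and 3 in all 10 ways, r averaged 0.0672 (range -0.12 to 0.236). Of the genes called, 10 were higher with exercise and lower with age, among them scpp7, against 0.787 for independent lists, and 7 were lower in both, among them NR1D1, PER1 (ENSDARG00000012499) and HSF2, against 0.509. The shared libraries favour calls in opposite directions. No overlap was counted in the simulations, so the values for independent lists do not allow for this.

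Averaged over both ages, exercise called 4097 genes, 2012 higher (49.1%) and 2085 lower. A change at 1 age alone can pass this test. On simulated counts changed in 1 group it found 28.4% of 2-fold and 62.1% of 4-fold changes. KLF8 rose by 2.44 (SE 0.29, adjusted p = 9.63e-05), the transglutaminase tgm5l by 3.21 (SE 0.47), loxl2a by 2.32 (SE 0.33), evpla by 1.85 (SE 0.28), PPL by 1.41 (SE 0.20), the basement membrane collagen COL4A1 by 0.81 (SE 0.15), COL10A1 (ENSDARG00000054753) by 1.19 (SE 0.26), VEGFA (ENSDARG00000103542) by 1.29 (SE 0.24), KLF4 by 2.07 (SE 0.46), sesn2 by 0.93 (SE 0.18), and FOXO1 by 1.88 (SE 0.29, ENSDARG00000061549) and 0.73 (SE 0.13, ENSDARG00000099555). NR1D1 fell by 2.38 (SE 0.27), the squalene epoxidase SQLE (ENSDARG00000063319) by 2.80 (SE 0.73), CYP7A1 by 2.59 (SE 0.40) and HSF2 by 0.87 (SE 0.10). In the dermal matrix list 19 of 34 genes rose (21 adjusted over the list alone, adjusted p = 5.75e-08), and in the oxidative phosphorylation list 28 of 103 rose and 1 fell (53 and 1 adjusted over the list alone, adjusted p = 8.88e-10), UQCRFS1 by 0.40 (SE 0.10). Both lists had adjusted p = 0.665 with an estimated correlation. All 17 genes named here kept the call in the 20 fits without a library. The share that was higher was 23.7% of 1079 genes on the deposited RPKM and 20.9% with own totals, and the count was 2611 with the muscle covariate and 4 with surrogate variables.

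Averaged over exercise, age called 4218 genes, 2354 higher (55.8%) and 1864 lower. A change in exercised or unexercised fish alone can pass here too. With simulated changes in 1 group the test found 25.4% of 2-fold and 63.6% of 4-fold changes. COX4I2 rose by 0.96 (SE 0.11, adjusted p = 2.43e-05), cd79a by 2.02 (SE 0.39), igic1s1 by 2.12 (SE 0.47), plvapb by 0.88 (SE 0.13), the complement gene c7a by 1.03 (SE 0.21), TLR2 by 0.96 (SE 0.18), IRF7 by 1.47 (SE 0.38) and igf2b by 0.70 (SE 0.13). CRY2 fell by 1.09 (SE 0.10, adjusted p = 3.93e-06), dbpa by 1.72 (SE 0.17), NDUFS1 by 0.58 (SE 0.09), UQCR10 by 0.65 (SE 0.11), AGR2 by 1.2 (SE 0.20), the mucin muc5.2 by 0.70 (SE 0.17), PMVK by 1.47 (SE 0.37), STARD4 by 0.85 (SE 0.17), DEPTOR by 1.22 (SE 0.20) and aox5 by 0.72 (SE 0.15). Of 103 oxidative phosphorylation genes 55 fell and 1 rose (67 and 2 adjusted over the list alone, adjusted p = 1.84e-16), and of 42 cell cycle genes 29 rose (34 adjusted over the list alone, adjusted p = 5.85e-14). Both lists had adjusted p = 0.426 with an estimated correlation. All 18 genes named here kept the call in the 20 fits without a library. The share that was higher was 87.2% of 1791 genes on the deposited RPKM and 79.7% with own totals, and the count was 68 with surrogate variables.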

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

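The tests of explanations in this part were chosen only after the results were seen. Single libraries that lay far from the other 4 of their group were found in 16 of 252 groups of values examined, where chance gives about 1 in 20 groups, or 12.6. Among list scores (mean log2 CPM) these were mucous cell genes in exercised 1-year replicate 1 (4.2, nearest other 4.55), scale osteoblast genes in unexercised 3-year replicate 1 (4.48, nearest 3.75), melanophore genes in unexercised 3-year replicate 3 (0.74, nearest 1.38) and erythrocyte genes in exercised 1-year replicate 2 (4.05, nearest 3.13). Further ones were T cell genes in exercised 3-year replicate 4 (3.27, nearest 1.98), Schwann cell genes in unexercised 3-year replicate 5 (4.78, nearest 4.53), clock genes in unexercised 3-year replicate 1 (4.64, nearest 4.85) and hypoxia genes in exercised 1-year replicate 2 (5.03, nearest 4.77). Among gene levels, in CPM, they were apoa2 (235, nearest 77.0) and tfa (388, nearest 137) in unexercised 3-year replicate 4, tfa in unexercised 1-year replicate 4 (120, nearest 44.9), cfp in exercised 1-year replicate 5 (9.79, nearest 7), myhz2 in exercised 1-year replicate 2 (9.35, nearest 3.99), MMP9 in exercised 3-year replicate 4 (531, nearest 229) and mki67 in unexercised 3-year replicate 3 (90, nearest 45.6). mhc2dga stood at 205 in unexercised 1-year replicate 3, against 0.216 at most in the other 4.

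The exercise effect differed between ages by the test of the difference for ENSDARG00000104886 (1.8) and, with camera's preset correlation, for 18 lists, none of which passed with an estimated correlation. With the hepatocyte covariate the matrix protease, osteoclast, mitochondrially encoded, fatty acid oxidation and antioxidant lists did not pass. Medians of the difference, 3 years minus 1 year, were above 0 for matrix protease (0.29), osteoclast (0.52), fast skeletal muscle (0.69), neutrophil (0.43), macrophage (0.87), cell cycle (0.73), unfolded protein response (0.36), inflammation (0.47) and interferon response genes (0.80). They were below 0 for basal keratinocyte (-0.34), superficial keratinocyte (-0.32), iridophore (-0.19), mitochondrially encoded (-0.26), ribosomal protein (-0.24), fatty acid oxidation (-0.29), complement and antimicrobial (-1.5), antioxidant (-0.26) and growth and insulin signalling genes (-0.21).

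Liver-type transcripts were higher with exercise at 1 year: 24 of 28 hepatocyte genes passed, with a median log2 change of 3.08. A scaling shift from the counts taken by the most abundant genes was argued against by size alone. Scaling moved the median of all genes by 0.15, while the hepatocyte median had a bootstrap interval over genes of 2.72 to 3.31. The list was made after the data were examined, and that interval leaves out the spread between libraries. Liver tissue in some dissected samples may account for the higher levels: with group means removed, the hepatocyte genes correlated over the 20 libraries with a median pairwise r of 0.917 (lowest -0.349). In exercised 1-year replicate 3 the most abundant of them were tfa at 1259 CPM, apoa2 at 1091 CPM and apoa1b at 893 CPM, against 69.7, 62.0 and 73.1 CPM in replicate 4. A shared response of these genes in skin would also make them correlate, so a biological difference stays open, as untested.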

How the results depend on the processing

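Upper-quartile factors and both filters for the gene lists, the RPKM with own totals and the hepatocyte covariate were chosen after seeing the data; the other alternatives were chosen before the data were examined. Of 171 values of single genes named as past the test, 169 kept direction and call with RLE scaling, 170 with upper-quartile scaling, 170 of 170 with DESeq2, 157 of 157 with the strict filter, 156 without a filter, 141 with limma voom, 149 with the muscle covariate, 125 with the hepatocyte covariate, 151 on RPKM with own totals, 96 on the deposited RPKM, 98 of 133 with the compared groups alone and 21 with surrogate variables. With surrogate variables 2 reversed in age with exercise, nkl.2 (-0.39) and srebf2 (0.033). In fits without a library, 128 of 171 kept the call throughout and none reversed. The losses were uneven between comparisons. Of the 22 values that lost the call with the muscle covariate, 21 were for exercise at 3 years. Of the 29 values for that comparison, 6 kept the call with limma voom, 8 with the hepatocyte covariate and 6 with the compared groups alone.

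Counts of called genes that moved by over 1.5 times follow; the cause was not tested. Exercise at 1 year called 433 on the deposited RPKM, 2 with surrogate variables and 1952 with the hepatocyte covariate. Exercise at 3 years called 1298 with DESeq2, 39 with voom, 27 on the deposited RPKM, 50 with the compared groups alone, 54 with the muscle covariate, 9 with surrogate variables and 57 with the hepatocyte covariate. Age without exercise called 842, 933, 46 and 129 with DESeq2, voom, the deposited RPKM and the compared groups alone, and 77 with the hepatocyte covariate. Age with exercise called 578 on the deposited RPKM, 1673 with the compared groups alone, 16 with surrogate variables and 1927 with the hepatocyte covariate. The difference between ages called 2 with RLE, upper-quartile scaling, the strict filter, voom, the muscle covariate and own-total RPKM, 498 with DESeq2, and 0 without a filter, on the deposited RPKM, with surrogate variables and with the hepatocyte covariate. Averaged exercise called 1079 on the deposited RPKM, 2611 with the muscle covariate and 4 with surrogate variables, and averaged age 1791 on the deposited RPKM and 68 with surrogate variables.

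Without 1 library the counts ran from 1909 to 3534 for exercise at 1 year, 42 to 390 at 3 years, 43 to 393 for age without exercise, 2174 to 4148 with exercise, 0 to 39 for the difference, 3041 to 4649 for averaged exercise and 3137 to 4875 for averaged age. The correlation of exercise effects between ages ran from 0.193 to 0.305. It was 0.394 over genes of at least 5 CPM and 0.164 with the muscle covariate. That of age effects ran from 0.376 to 0.486, and was 0.392 with the muscle covariate. Of 135 list calls in the 7 comparisons, 0 held with an estimated correlation, whose construction widens the error of lists with correlated members. The list calls ran from 128 to 147 without 1 library. With the hepatocyte covariate the complement list reversed for exercise at 1 year (-0.27), the difference (0.59) and, by camera's direction though not its median (0.065), averaged exercise. With the muscle covariate the fast skeletal muscle list reversed for exercise at 3 years (-0.06), the difference (-0.043) and averaged exercise (-0.072), as the covariate is that list's own score. Exercise at 3 years against age had r = 0.0672 once no library was shared. No paired analysis was possible because the labels carry no replicate numbers.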

Other observations

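All tests of explanations in this part, and the counts over other splits, were chosen only after the results were seen. Further lists, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and camera, had these results with age among exercised fish. In the antioxidant list 11 of 40 genes fell and 1 rose (15 and 2 adjusted over the list alone, adjusted p = 0.000118), in the glucocorticoid response list 5 of 22 fell and 1 rose (5 and 2 adjusted over the list alone, adjusted p = 0.0139), and in the iridophore list 4 of 11 fell (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.00516). In the antigen presentation list 4 of 31 rose (3 adjusted over the list alone, adjusted p = 0.0278). With an estimated correlation these were adjusted p = 0.368, adjusted p = 0.444, adjusted p = 0.368 and adjusted p = 0.608. With exercise at 3 years 2 of 25 wound and regeneration genes rose, lepb and TNC (ENSDARG00000021948), and 6 adjusted over the list alone (adjusted p = 0.00278, and adjusted p = 0.418 with an estimated correlation). With exercise at 1 year 8 of 35 growth and insulin signalling genes rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.00507, and adjusted p = 0.785 with an estimated correlation).

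Clock genes changed in all 4 pairwise comparisons. Levels of the sets of clock and light-induced genes below are means of log2 of CPM plus 1. The labels do not give the hour of sampling, and another hour would move genes in phase with bmal (8) against those in phase with nr1d (11). That difference of arms was 1.64 (SE 0.21) with age without exercise and 2.71 (SE 0.21) with age among exercised fish (two-sided exact permutation p = 0.00794 each, n = 5), the bmal arm being higher and the nr1d arm lower in both (exact p = 0.00794 each), so another hour of sampling may account for both. With exercise at 3 years it was 1.00 (SE 0.26, exact p = 0.00794), from the nr1d arm alone, which fell by 1.00 (SE 0.22), as the bmal arm had no clear change (exact p = 0.984), and an hour of sampling and exercise cannot be told apart there because the arms did not move against each other. With exercise at 1 year it was -0.08 (SE 0.15, exact p = 0.611), both arms being lower. The bmal arm changed by -0.65 (SE 0.19, exact p = 0.0238) and the nr1d arm by -0.57 (SE 0.20, exact p = 0.0159). Another hour was taken to move these arms against each other, and they fell together. The difference of arms was too uncertain for a verdict, so an hour of sampling and exercise cannot be told apart there. More light before sampling could account for part of the clock changes with exercise at 1 year, where 8 light-induced genes were higher by 0.37 (SE 0.16, exact p = 0.0317). It was argued against at 3 years, where they were lower (-0.23, SE 0.09, exact p = 0.0397). With age the light-induced genes were lower too, by -0.43 (SE 0.16, exact p = 0.0476) without exercise and -1.03 (SE 0.08, exact p = 0.00794) among exercised fish. Light was not tested as an explanation of the age differences. An effect of exercise or age on the clock stays open, as untested.

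The oxidative phosphorylation list was higher with exercise at both ages by camera with a preset correlation but not with an estimated one (adjusted p = 0.785 at 1 year and adjusted p = 0.572 at 3 years). Its score was higher by 0.30 (SE 0.12, two-sided exact permutation p = 0.0397, adjusted p = 0.159, n = 5) at 1 year and by 0.23 (SE 0.12, exact p = 0.0952, adjusted p = 0.239) at 3 years. The part of each difference that goes with a marker score is the slope within groups times the difference of that score. For the fast skeletal muscle score it was 0.06 (95% interval 0.03 to 0.09) at 1 year. That argues against fast skeletal muscle in the sample as the main cause there. The slow skeletal muscle score was higher by 0.53 at 1 year (exact p = 0.0317, adjusted p = 0.142). Its part was not computed, so slow muscle stays open there. For the fast skeletal muscle score the part was 0.18 (0.09 to 0.27) at 3 years, where more muscle in the sample is a candidate explanation. For the hepatocyte score, whose exercise difference at 3 years was -0.48, it was -0.03 (-0.08 to 0.03) at 3 years, which argues against liver tissue. At 1 year it was 0.10 (-0.11 to 0.32), an interval that holds both 0 and the whole difference, so liver tissue and exercise cannot be told apart there. An effect of exercise on skin cells stays open, as untested.

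Other splits of the same libraries into groups of the same sizes, 40 per comparison with the real one included, bear on chance. For exercise at 1 year 1 split, the real one, gave as many as 3227 genes (highest other 3), for exercise at 3 years 1 gave as many as 275 (highest other 30), and for age without exercise 1 gave as many as 201 (highest other 6). For age with exercise 1 gave as many as 3566, with 852 in the highest other. For averaged exercise 1 gave as many as 4097 (highest other 12) and for averaged age 1 as many as 4218 (highest other 25). For these 6 no other split drawn gave as many, which argues against chance. With 40 splits no share below 1 in 40 can be shown, so chance is not fully excluded. For the difference between ages 4 of the 40 splits gave at least the real 1 gene (highest other 9). Those splits exchanged exercise labels within each age, which takes away the exercise effect as well. They cannot decide whether the effect differs between ages, so chance cannot be excluded.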
